A study of Mus musculus with 16 samples.

How the data were processed

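Microglia are the resident macrophages of the brain. Per the labels' protocols, brains were digested to single cells and passed through a filter, myelin was taken away with antibody-coated magnetic beads, and cells carrying CD11b, a surface integrin of myeloid cells, were then collected on beads. Total RNA was turned into biotinylated cRNA and hybridised to Illumina arrays. The labels place 16 arrays in 6 groups. SIRT1F/F mice carry a floxed Sirt1 gene, and LysM-Cre/SIRT1F/F mice also carry a Cre recombinase inserted in the lysozyme gene Lyz2, which is active in myeloid cells. Both genotypes were labelled young or old, with 3 arrays in each of these 4 groups. TAU and TAU/LysM have 2 arrays each. The labels give no age for TAU and TAU/LysM, and those of TAU/LysM do not repeat the floxed genotype. The genetic background is given as a mix of BL6 and 129/Sv. The labels do not say that the replicates are separate animals, so the p-values measure the spread between these samples, which may be technical in young SIRT1F/F, old LysM-Cre and TAU. In the other 3 groups some arrays were near background (normalized level under 7) for Xist, expressed in females, or Eif2s3y, on the Y chromosome, and others were not, so these are not all repeats of 1 sample. The other 11 arrays had both transcripts, so the samples may be pools of both sexes, which the labels do not state.

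The authors deposited a table of probe intensity for the 16 arrays that, by its values, was neither background subtracted nor normalized between arrays. The scanner and its summary software are not given in the sources used here. The deposited table of log2 values equals quantile-normalized log2 intensity to within 5e-09, keeps every rank of the matching intensity column (lowest rank correlation 1), and has a median of 7.894 in every column, so its scale and centring are known from the values and no background subtraction entered it. Each array's median intensity lay between 202.9 and 283.6, its lowest between 126.2 and 167.2 and its brightest between 42456 and 49192. For these arrays their number limits the precision.

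The test fixed before the data were examined asked for neqc normalization and a filter on detection p-values, both of which need control probes or detection values that the intensity table used here does not hold. In their place, intensities were corrected with limma's normexp fitted on all probes of an array (offset 16), put on the log2 scale and quantile normalized. Each array's background was the mode of its log2 intensity with the spread of the values below that mode. A probe counted as above background where its upper normal tail was under 0.05 (1.645 such spreads above the mode), which 56.1% to 59.1% of the 25697 probes were on each array. The 16858 probes above background on at least 2 of the 16 arrays were tested. Arrays of 1 group correlated at 0.984 to 0.993 across these probes.

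Genes were named through the platform table given with the series. It gives 1 symbol for 23978 probes, several for 0 and none for 1719, which stay unnamed here. Of the probes, 23962 matched the GRCm38.p6 gene table by gene identifier, and 0 symbols changed. The tested probes with a symbol number 15840 and cover 11318 genes. That assembly was used for names and for gene neighbours, and no positions are printed because no build is given for the arrays.

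Each of 9 comparisons was a contrast of 1 limma fit (limma 3.58.1, R 4.3.3) with 6 group means over all arrays, 10 residual degrees of freedom and a prior of 3.72 from empirical Bayes. Values are log2 differences with their standard error (SE). A probe was called at a Benjamini-Hochberg adjusted p under 0.05. The genotype comparisons set LysM-Cre against SIRT1F/F arrays among the young, the old and the TAU samples, and averaged the 3 differences. The age comparisons set old against young within each genotype, and the difference of the age effects is the interaction. TAU was set against young and against old SIRT1F/F because its age is unknown. Where all arrays of 1 group were not well above background for a probe, the text gives "at least N-fold", the brighter group's mean against, per array of the dimmer group, the higher of the lowest signal well above background and the probe's own signal.

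The lists of genes, 34 in number with 635 entries, were fixed before the data were examined. Of the entries 572 matched a probe, 3 of them through an older or newer symbol, and 523 had a tested probe. They cover sirtuins, the IL-1 family and inflammasome, inflammatory cytokines and chemokines, NF-kB feedback targets, interferon-stimulated genes, homeostatic microglia, disease-associated microglia, complement and phagocytic receptors, antigen presentation, p53 targets and senescence, antioxidant and FOXO targets, DNA methylation machinery, cholesterol and lipid handling, lysosome and autophagy, alternative activation, oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins, cell cycle, circadian clock, and immediate early and dissociation response. Markers of other cells cover monocytes, border-associated macrophages, neutrophils, T and NK cells, B cells, astrocytes, neurons, the oligodendrocyte lineage, endothelial cells, mural and meningeal cells, choroid plexus and ependyma, and erythrocytes and platelets. A sex-linked list served as a sample check. A list was tested over its probe of highest mean per gene with limma's camera (preset correlation 0.01), adjusted over lists within a comparison, with camera at an estimated correlation and fry beside it. Members were counted over all probes and adjusted over the list alone.

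Replicate numbers come from the labels, which do not say that they pair samples. Deviations from the group means of same-numbered arrays correlated at 0.23 to 0.50 in the 3 pairs of young SIRT1F/F with young LysM-Cre, all over 0.1, so the numbers were taken to pair these arrays, from the data alone. Between no other 2 groups of 3 arrays were all pairs over 0.1, and the 2 TAU groups have too few pairs for this check.

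Genes were named by a rule fixed before the data were examined. It takes Sirt1, Lyz2, Mapt and Il1b in every comparison, up to 12 genes per direction with the largest change among called probes, up to 5 of smallest p where fewer were called, and up to 4 members per list described. A gene named for its own change is given at its probe of lowest p, and a gene named only as a list member at its list's probe.

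The fit was tested on simulated data in which 200 of 16858 probes were changed. For the young genotype comparison, with 3 arrays per group, 25% of probes changed by 0.5, 81% changed by 1 and 98% changed by 2 (log2) were recovered. For the TAU genotype comparison, with 2 arrays per group, the shares were 1%, 68% and 98.5%. Beside these, 0, 13 and 13 unchanged probes were called in the young comparison and 1, 8 and 11 in the TAU comparison. Where nothing was changed, 0 probes were called in both. A 0.3 shift of glycolysis was called, with 0 other lists. This does not test the preset correlation.

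Alternatives fixed before the data were examined were quantile normalization without background correction, the deposited log2 values, an offset of 50, no filter, a stricter filter (background p under 0.01 on every array of at least 1 group, 14434 probes), the replicate number as a block, only the groups compared, array weights, a trended and robust variance, 1 probe per gene, an estimated correlation in the list test, and each array left out in turn. Slide as a block was not run, because the files used here name no slide. Chosen after seeing the data were the level of Xist as a covariate, the level of the oligodendrocyte list as a covariate, and a fit without 5 arrays near background for Xist or Eif2s3y. That fit keeps 1 array each of young LysM-Cre, old SIRT1F/F and TAU/LysM, and leaving out a TAU or TAU/LysM array leaves 1 in its group. A lone array is assumed to vary like the other groups, and the small group alone can end a call.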

Results

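Gene expression was measured on 16 arrays of CD11b-selected mouse brain cells, labelled microglia. The groups were young SIRT1F/F, young LysM-Cre/SIRT1F/F, old SIRT1F/F and old LysM-Cre/SIRT1F/F with 3 arrays each, and TAU and TAU/LysM with 2 arrays each. LysM-Cre/SIRT1F/F is called LysM-Cre below. The series asks what SIRT1, a protein deacetylase that uses NAD, does in microglia of young and aged mice and in dementia models, and its title names IL-1beta.

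Sirt1 itself was not called different between the genotypes. Its level was 10.04 ± 0.19 (SD, log2, n = 3) in young SIRT1F/F and 10.07 ± 0.03 in young LysM-Cre, 9.72 ± 0.13 and 9.78 ± 0.18 in the old groups, and 9.58 ± 0.15 in TAU against 9.63 ± 0.14 in TAU/LysM (n = 2 each). The genotype difference was 0.03 ± 0.12 (SE) in young, 0.07 ± 0.12 in old and 0.05 ± 0.15 in TAU samples, and averaged 0.05 (limma adjusted p = 0.767). Where the probe lies relative to the floxed part of the gene is not known here, so its level checks nothing about the deletion. Il1b, the IL-1beta gene, read 24477 to 35565, where differences may be compressed, and was called in none of the 9 comparisons. Some alternatives called it with age in SIRT1F/F and in TAU against young SIRT1F/F. Its average genotype difference was 0.14 (adjusted p = 0.201). In the young groups it lay at 14.58 and 14.77. The sex-linked genes gave a sample check. Xist, transcribed from the inactive X chromosome, lay at 10.21 to 11.89 on 13 arrays and at 6.22, 6.32 and 6.08 on young LysM-Cre 3, old SIRT1F/F 2 and old SIRT1F/F 3. Eif2s3y, on the Y chromosome, lay at 9.58 to 11.47 except at 5.32 on young LysM-Cre 2 and 5.07 on TAU/LysM 1, so that most arrays showed both.

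**Figure D1:**
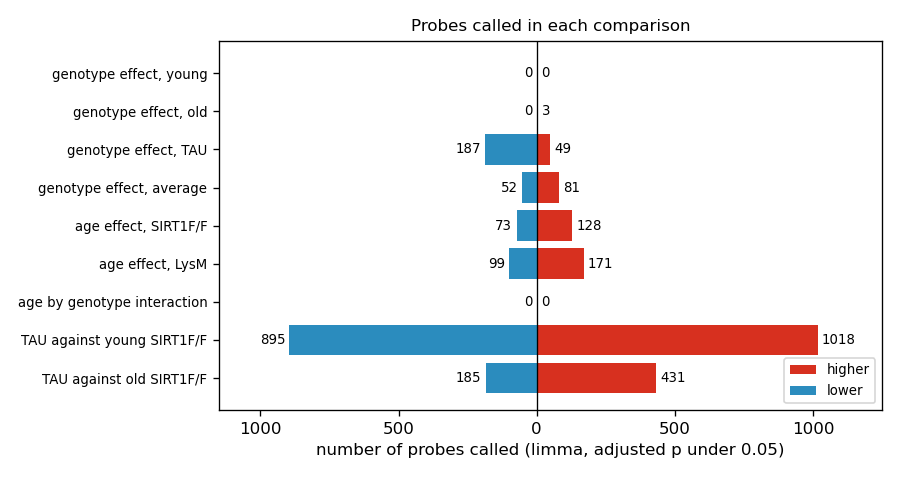
Number of probes called at adjusted p under 0.05 by limma in each of the 9 comparisons (horizontal axis, probes; higher in red to the right, lower in blue to the left). Counts run from 0 for the young genotype comparison and the interaction to 1018 higher and 895 lower for TAU against young SIRT1F/F.

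In young mice, no single gene was called different between LysM-Cre and SIRT1F/F samples. The smallest adjusted p was 0.277, shared by Lyz1, a lysozyme gene paired with Lyz2, and Ly6d, a lymphoid surface antigen. Lyz1 was 1.90 ± 0.32 and 2.04 ± 0.37 higher on 2 probes with LysM-Cre. The first went from 9.53 ± 0.85 (SD, n = 3) to 11.43 ± 0.31, while another differed by -0.08. That probe read 36401 to 45044 on all arrays, near a ceiling of 42456 to 49192. In old SIRT1F/F the others read 250 to 381, so it may read other RNA and gives no size. Ly6d differed by 0.75 ± 0.12. Lyz2, the Cre site, differed by -0.38 ± 0.1 (adjusted p = 0.533), its probes by -0.79 to -0.37. Other genes of small p were F10, coagulation factor X, at 0.92, the chemokine Ccl24 at 0.71 and the B cell cofactor Pou2af1 at 1.00. With lower values stood Tnfsf10, which encodes the death ligand TRAIL, at -0.59. F10 and Pou2af1 were above background on 1 of 3 young SIRT1F/F arrays and Tnfsf10 on 1 of 3 young LysM-Cre arrays. Mapt, the gene of tau, differed by -0.10.

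As groups, markers of neutrophils, B cells and monocytes were higher in young LysM-Cre samples, while the T and NK cell list was not called (median 0.10, adjusted p = 0.298). Camera called the neutrophil list higher, with 0 of its 16 measured members called and a median of 0.63 (adjusted p = 1e-06, and adjusted p = 0.46 with an estimated correlation), Elane at 1.30, Lcn2 at 0.82 and Ltf at 0.66 among them. The B cell list had a median of 0.27 (adjusted p = 1.82e-05, and adjusted p = 0.12 with an estimated correlation), with 4 of 9 members higher when adjusted over the list alone and none over all probes. Among them were Vpreb3 (above background on 1 of 3 young SIRT1F/F arrays) at 1.15 and Cd79a at 0.60. The monocyte list (median 0.32) and the cell cycle list (median 0.16) were called higher at 0.00548 each, and both had an adjusted p = 0.46 with an estimated correlation. Inflammatory cytokines and chemokines stood at 0.16, with Cxcl1 at 1.11 and Cxcl2 at 0.60, both neutrophil attractants, and NF-kB feedback targets at 0.15. Both lists had an adjusted p of 0.0203 by camera, which was 0.46 and 0.66 with an estimated correlation. Alternative activation (median 0.09, adjusted p = 0.029, and adjusted p = 0.46 with an estimated correlation) included Il10 at 0.70. Choroid plexus markers had a median of 0.25 (adjusted p = 0.0429, and adjusted p = 0.54 with an estimated correlation). The homeostatic microglia list, genes of resting microglia, was called lower at a median of -0.07 (adjusted p = 0.0472, adjusted p = 0.0668 with the replicate number as a block, and adjusted p = 0.54 with an estimated correlation), with P2ry12, a purine receptor of microglial processes, at -0.36 and Gpr34 at -0.24. Limma called 0 probes over the comparison, with 1329 at an unadjusted p under 0.05. That fit does not pair the young arrays by number. Without young SIRT1F/F 1, 8 probes were called. Of the 9 list calls only those of neutrophils and B cells held without any 1 array. The others went with single arrays, and 2, 7, 4, 3, 4 and 3 were lost without young SIRT1F/F 1, 2 and 3 and young LysM-Cre 1, 2 and 3.

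In old mice, Lyz1 separated the genotypes. It rose by 3.73 ± 0.37 with LysM-Cre (adjusted p = 0.00163), from 7.43 ± 0.33 (SD, n = 3) to 11.16 ± 0.26, and its other responding probe by 3.02, while the probe near the ceiling differed by -0.04. Eif1ax, an X-linked translation initiation factor, rose by 0.80 ± 0.11 (adjusted p = 0.0367). It was not well above background in old SIRT1F/F, which gives at least 1.11-fold. Those 3 probes were all that limma called, none of them lower, with 1090 probes at an unadjusted p under 0.05. Xist was near background on 2 of the 3 old SIRT1F/F arrays and at 10.21 to 11.1 in old LysM-Cre. Sex make-up may thus differ with genotype here. Lyz2 differed by -0.31 ± 0.1 and Il1b by 0.11, neither called. The next by p were F10 at 0.78 (adjusted p = 0.582) and Tbx6 above 0, and Tceal1 at -0.52 (adjusted p = 0.307), Hrh2, the histamine H2 receptor, and Hal, histidine ammonia-lyase, at -1.46 below it. Hrh2 and Hal were above background on 2 of 3 old LysM-Cre arrays.

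Interferon-stimulated genes formed the group with the strongest camera call in old mice. All 20 measured members had positive differences, with a median of 0.34 (adjusted p = 3.97e-09, and adjusted p = 0.34 with an estimated correlation) but none called over all probes or when adjusted over the list alone. The RNA sensors Oas2 at 0.90 and Oasl2 at 0.63 and the antiviral Rsad2 at 0.50 had the smallest p. Neutrophil markers were again higher (median 0.59, adjusted p = 3.31e-07), with Ifitm6 at 0.80 and Mmp9 at 0.78. So were monocyte markers (median 0.49, adjusted p = 0.000245), with Hp at 0.81. Homeostatic genes were lower by camera (median -0.11, adjusted p = 0.000245), with the transcription factor Mef2c at -0.40 and the fractalkine receptor Cx3cr1 at -0.28. Glycolysis was higher (median 0.13, adjusted p = 0.00161), with Pkm at 0.31. Markers of erythrocytes and platelets were lower (median -0.53, adjusted p = 0.0204), with Hbb-b2 at -0.73. With an estimated correlation these lists had adjusted p = 0.47, 0.34, 0.34, 0.091 and 0.33. The IL-1 family and inflammasome list was not called (median -0.04, adjusted p = 0.827), nor were the sirtuins. Eif1ax lost its call without any 1 of the 6 old arrays, at an adjusted p of 0.0686, 0.362 and 0.255 without old SIRT1F/F 1, 2 and 3 and of 0.155, 0.261 and 0.149 without old LysM-Cre 1, 2 and 3. The erythrocyte list lost its call without old SIRT1F/F 2 (adjusted p = 0.158) or old LysM-Cre 3 (0.0801). In the fit without the 5 arrays near background for Xist or Eif2s3y, which keeps 1 old SIRT1F/F array, assumed to vary like the other groups, 0 probes were called, with 546 at an unadjusted p under 0.05 and Lyz1 at 4.06 (adjusted p = 1). With 1 probe per gene limma also called 0, with 771 at an unadjusted p under 0.05, where the probe kept for Lyz1 was the one near the ceiling and Eif1ax was not called.

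**Figure D2:**
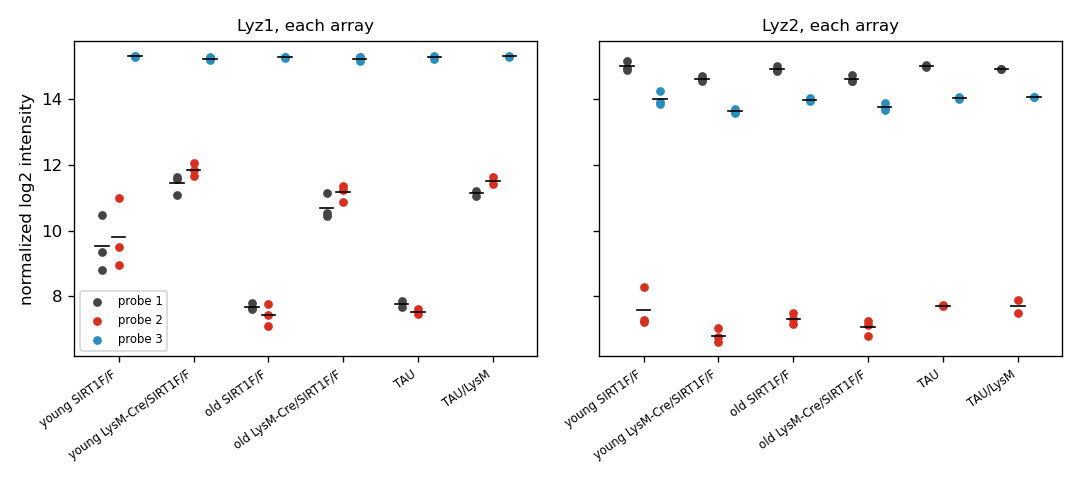
Normalized log2 intensity (vertical axis) of the probes of Lyz1 and Lyz2 on each of the 16 arrays by group (dots, arrays; lines, group means). On its responding probes Lyz1 lies near 11 in every LysM-Cre group and, on 1 of them, at 7.43 in old SIRT1F/F and 7.53 in TAU, while Lyz2 on its bright probe lies near 15 throughout.

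TAU/LysM arrays had lower oligodendrocyte and choroid plexus markers and higher interferon-stimulated genes than TAU arrays. Mbp, the myelin basic protein, fell by 4.62 ± 0.36 (adjusted p = 2.29e-05), from 11.74 in TAU to 7.12 in TAU/LysM, though another of its probes differed by 0.10. Olig1, a transcription factor of the oligodendrocyte lineage, fell by 2.98 ± 0.22 and Car2, carbonic anhydrase 2, by 2.45 ± 0.19, both at 2.29e-05. Bcas1, of early myelinating cells, fell by 4.52 ± 0.73 (adjusted p = 0.00802) and Plekhb1 fell by 3.47 ± 0.41. The myelin genes Mobp, Mog, Opalin, Fa2h and Omg were not well above background in TAU/LysM and fell at least 12.6-fold, 4.75-fold, 4.26-fold, 3.9-fold and 3.81-fold. Of 13 measured oligodendrocyte genes 6 fell over all probes, and 7 fell and 1 rose when adjusted over the list alone (median -0.98, adjusted p = 8.65e-10, and adjusted p = 0.089 with an estimated correlation). Of 7 choroid plexus and ependyma genes 5 fell (median -1.58, adjusted p = 7.04e-08, and adjusted p = 0.18 with an estimated correlation), among them the folate receptor Folr1 at -2.35 ± 0.38, Kl at -2.19, Clic6 at -2.10 and Calml4 at -1.52. Sostdc1, a secreted BMP antagonist of the choroid plexus, fell by 2.50 ± 0.37. Of 15 astrocyte genes 2 fell, Aldoc by 0.95 ± 0.17 and Gfap, the astrocyte filament protein, at least 1.5-fold (list median -0.51, adjusted p = 0.000558, and adjusted p = 0.21 with an estimated correlation). Neuron markers (median -0.35, adjusted p = 0.0041, and adjusted p = 0.18 with an estimated correlation) included Map2, which fell by 0.92. Endothelial markers had a median of -0.47 (adjusted p = 0.000887, and adjusted p = 0.41 with an estimated correlation), and the mural and meningeal list was not called, with a median of 0.05 but a mean of -0.16. Mapt fell on 1 of its 3 tested probes, by 1.26, and differed by -0.91 (adjusted p = 0.0651, or 0.0426 with array weights) and -0.09 on the others, the first of these above background on 1 of 2 TAU/LysM arrays.

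Interferon-stimulated genes and antigen presentation were higher in TAU/LysM than in TAU. Of 20 measured interferon-stimulated genes 4 rose over all probes and 17 when adjusted over the list alone (median 0.70, adjusted p = 8.03e-14, and adjusted p = 0.18 with an estimated correlation). Oas2 rose by 1.73 ± 0.35 (adjusted p = 0.0261), Irf7, a master regulator of type I interferon, by 1.37 ± 0.28 (adjusted p = 0.0301), and Stat2 and Mx1 by 1.04 each. Of 20 antigen presentation genes, Nlrc5, the transactivator of MHC class I, rose by 1.47, and 11 were higher when adjusted over the list alone (median 0.42, adjusted p = 4.04e-07, and adjusted p = 0.21 with an estimated correlation). Lyz1 again rose the most, by 3.98 ± 0.45 (adjusted p = 0.000557), and Igfbp6 rose by 1.62 ± 0.25 and Slc47a1, an organic cation exporter, by 1.42. Disease-associated microglia genes, which mark microglia at plaques and in degeneration, had a median of 0.26 (adjusted p = 6.14e-05, and adjusted p = 0.18 with an estimated correlation), with Gpnmb, a glycoprotein of lipid-laden phagocytes, higher by 1.17 ± 0.24 (adjusted p = 0.0308) and Lgals3 at 0.70 (adjusted p = 0.099). Homeostatic genes had a median of -0.21 (adjusted p = 1.03e-05, and adjusted p = 0.18 with an estimated correlation). Higher by camera were neutrophils at a median of 0.66 (3.5e-05), monocytes at 0.61 (0.00141), and T and NK cells at 0.33 (0.00285). So were border-associated macrophages at 0.52 (8.33e-06). With an estimated correlation these lists had adjusted p = 0.36, 0.26, 0.24 and 0.24. Oxidative phosphorylation at -0.10 and cytokines at 0.18 were called at 0.0306 and 0.0413, which became adjusted p = 0.26 and adjusted p = 0.34 with an estimated correlation. The erythrocyte and platelet list was not called (median 0.51, adjusted p = 0.211), with 2 members higher and 1 lower when adjusted over the list alone, and TAU/LysM 1 stood apart in it from the other 3 of these arrays (0.667 against -0.483 on TAU/LysM 2 and -0.581 and -0.609 on the TAU arrays). Its Hba-a1, a haemoglobin gene, lay at 14.55 against 10.05 on TAU/LysM 2 and 10.03 and 10.14 on the TAU arrays. Il1b differed by 0.13 (adjusted p = 0.689) and Lyz2 by -0.08, the IL-1 family list by a median of 0.06 (adjusted p = 0.37) and the sirtuins by -0.16 (adjusted p = 0.133). Limma called 49 probes higher and 187 lower with 2 arrays per group. Of 34 called genes named by the rule, 11 held without any 1 array (Lyz1, Mbp, Mobp, Mog, Opalin, Olig1, Omg, Car2, Fa2h, Plekhb1 and Prr18). Of the calls 22, 16, 10 and 21 were lost without TAU 1, TAU 2, TAU/LysM 1 and TAU/LysM 2. The cytokine and oxidative phosphorylation lists lost their calls without TAU 1 (adjusted p = 0.29 and 0.0669) or TAU/LysM 2 (0.468 and 0.103), and the endothelial list without TAU/LysM 2 (0.391). Without TAU 1, TAU 2 or TAU/LysM 2 limma called 28, 113 or 39, with the level of the oligodendrocyte list as a covariate 1, and without the 5 arrays of low Xist or Eif2s3y, which keeps 1 TAU/LysM array, 32.

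Averaged over the young, old and TAU samples, LysM-Cre went with more Lyz1 and higher interferon-stimulated genes and neutrophil and monocyte markers. Oligodendrocyte transcripts averaged lower through their high level on the TAU arrays. Lyz1 rose by 3.25 ± 0.23 (adjusted p = 1.46e-05), F10 by 0.91 ± 0.1 (adjusted p = 0.00082), Oas2 by 1.05 ± 0.18 (adjusted p = 0.0201), Igfbp6 by 0.85 (adjusted p = 0.00874), the neutrophil protease inhibitor Stfa1 by 1.19, Plac8 by 0.84 and the arginase gene Arg2 by 0.82. Irf7 rose by 0.80, Stat2 by 0.53, the anti-inflammatory cytokine gene Il10 by 0.77, the transcription factor Nfil3 by 0.48, Lgals3 by 0.46, and the B cell genes Ly6d by 0.51 and Cd79a by 0.42. Mbp fell by 1.83 (adjusted p = 0.000433), Olig1 by 1.19 (adjusted p = 0.000384) and Aldoc by 0.50. Mobp and Mog were called lower too, but were not well above background in several groups, so no size is given, and F10 and Ly6d were not well above background in TAU, so that their values are not exact. The Mbp effect was lower in TAU than in young samples by a tested difference of -4.28, and than in old samples by -4.10. P2ry12 at -0.37 and Lyz2 at -0.26 ± 0.06 (adjusted p = 0.0551 each), and Axl at 0.49 and Cxcl2 at 0.45 (0.0506 each), were not called. Lyz2 lay close to the threshold and was called lower in 8 of the alternatives fixed beforehand, at an adjusted p from 0.0153 with a trended and robust variance to 0.0473, and without young LysM-Cre 2 (0.0443).

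Camera called 17 of the 34 lists in this average, none of them with an estimated correlation, and fry called 13. Higher were interferon-stimulated genes (3 members over all probes, 17 when adjusted over the list alone, median 0.38, adjusted p = 3.33e-12). So were neutrophils (none and 12, median 0.64, 1.54e-09), antigen presentation (none and 12, median 0.22, 1.82e-05) and monocytes (1 and 7, median 0.41, 2.35e-05). With an estimated correlation these lists had adjusted p = 0.15, 0.26, 0.26 and 0.2. Border-associated macrophages at a median of 0.26 (0.000608), cell cycle at 0.14 (0.00608), T and NK cells at 0.23 (0.0116), disease-associated microglia at 0.09 (0.00479), cytokines at 0.11 (0.00608) and NF-kB feedback targets at 0.15 (0.0144) were higher too, with an adjusted p of 0.26 to 0.43 with an estimated correlation. So were B cells at 0.21 (0.00164), glycolysis at 0.07 (0.0179) and alternative activation at 0.12 (0.0144), with adjusted p = 0.15, 0.15 and 0.26 with an estimated correlation. Lower were the oligodendrocyte lineage (5 members over all probes, median -0.38, 7.57e-06) and homeostatic microglia (4 when adjusted over the list alone, median -0.12, 1.98e-06), each with adjusted p = 0.15 with an estimated correlation. So were astrocytes at -0.16 (0.0166, and adjusted p = 0.3 with an estimated correlation) and choroid plexus at -0.33 (0.0372, and adjusted p = 0.4 with an estimated correlation). The backgrounds went apart in these averages. Choroid plexus medians were 0.25 in young, 0.30 in old and -1.58 in TAU samples, and oligodendrocyte medians 0.04, -0.04 and -0.98. Not called were sirtuins at -0.10, endothelial cells at -0.15, neurons at -0.04, DNA methylation machinery at 0.05 and oxidative phosphorylation at -0.04, all at an adjusted p of 0.115. Immediate early genes at 0.06 (0.12), cholesterol and lipid handling at 0.08 (0.141), antioxidant and FOXO targets at 0.03 (0.25), circadian clock at 0.02 (0.266), sex-linked genes at -0.39 (0.311), ribosomal proteins at -0.02 (0.35), p53 targets and senescence at 0.03 (0.354), lysosome and autophagy at 0.01 (0.578), mural and meningeal cells at 0.15 (0.669), and erythrocytes and platelets at 0.05 (0.773) were not called either. The IL-1 family list had a median of -0.02 but a mean of 0.03 and a positive test direction (0.754), and complement and phagocytic receptors a median of 0.01 with a mean of -0.04 and a negative one (0.773). Limma called 81 probes higher and 52 lower with 3259 at an unadjusted p under 0.05. Of 32 called genes named by the rule, 12 held without any 1 array (Lyz1, F10, Igfbp6, Ly6d, Mbp, Mobp, Mog, Olig1, Opalin, Prr18, Fa2h and Car2). TAU/LysM 2, TAU 1, old SIRT1F/F 3 and old LysM-Cre 3 cost the most when left out, with 20, 18, 17 and 17 calls lost. Of the 17 list calls 12 held without any 1 array. Those of cytokines, NF-kB feedback targets, glycolysis, astrocytes and choroid plexus did not, with 4 lost without TAU/LysM 2 or young LysM-Cre 2, 2 without young SIRT1F/F 1, old SIRT1F/F 1 or TAU 1, and 1 without TAU 2 or old LysM-Cre 1 or 2. The count of probes was 479 without young SIRT1F/F 1, 423 without young LysM-Cre 2, and 72 to 77 without young SIRT1F/F 2, young LysM-Cre 1 or TAU 2. It was 41 to 62 without young LysM-Cre 3, old SIRT1F/F 3 or old LysM-Cre 1, 2 or 3, 28 without TAU 1 or TAU/LysM 2, and 0 without the 5 arrays of low Xist or Eif2s3y, which leaves 1 array in 3 of the 6 groups, with 2107 at an unadjusted p under 0.05.

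**Figure D3:**
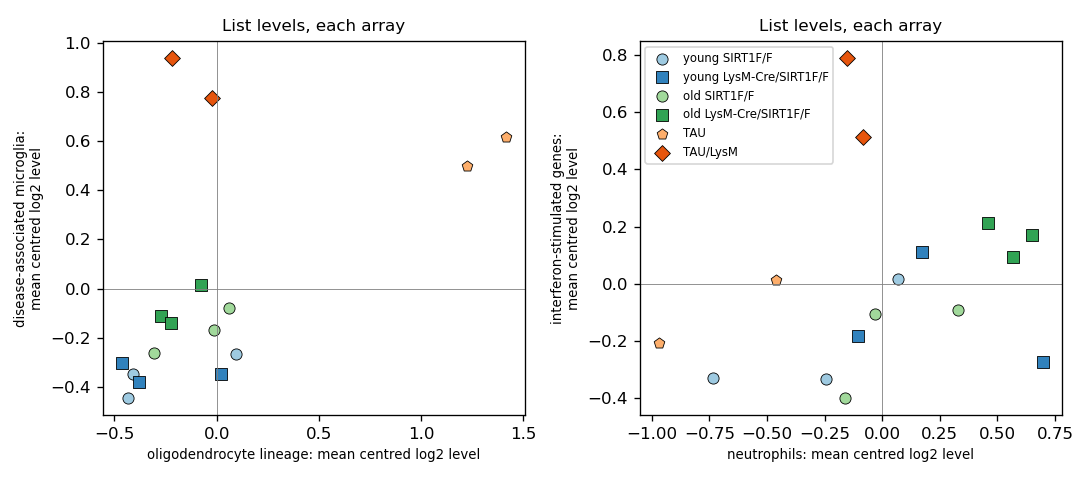
Mean level of gene lists per array, centred log2 over the list's genes, by group (1 point per array, 16 arrays). On the left the disease-associated microglia list (vertical) is set against the oligodendrocyte list (horizontal), where both TAU arrays lie far to the right and both TAU/LysM arrays do not, and on the right interferon-stimulated genes (vertical) against neutrophil markers (horizontal).

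With age, SIRT1F/F microglia had more Gbp2b, Scara3 and Tnfsf9 and less Il10 and Cd55. Gbp2b, an interferon-inducible GTPase, rose by 2.89 ± 0.59 (adjusted p = 0.032), the scavenger receptor Scara3 by 1.75 ± 0.28, Tnfsf9, which encodes the costimulatory ligand 4-1BBL, by 1.64 ± 0.24, Igfbp5 by 1.63 ± 0.3 and Slc47a1 by 1.58 ± 0.22 (adjusted p = 0.00979). Nbl1, a secreted BMP antagonist, had the smallest adjusted p of these, 0.00148. Gbp2b, Slc47a1 and Hbb-b2 were above background on 2 of 3 young arrays. Vwf, von Willebrand factor, rose by 1.55 ± 0.33, Ltbp4 by 1.52, the haemoglobin gene Hbb-b2 by 1.53, and Fbln1 by 1.55 on 1 of 3 probes that ranged from 0.38. Il10 fell by 1.82 ± 0.24 and Cd55, which limits complement, by 1.77 ± 0.23 (adjusted p = 0.00722 each). Lyz1 fell by 2.38 ± 0.37 (adjusted p = 0.0108) and on its probe near the ceiling by 0.04 without a call. Hmox1, haem oxygenase 1, fell by 1.55 ± 0.34, Hspa1l by 1.25 and the lectins Clec4a1 by 1.19 and Clec4n by 1.10. Il1a, the partner cytokine of IL-1beta, rose by 1.03 ± 0.19 (adjusted p = 0.0212), the only 1 of 15 genes of the IL-1 family list called, while Il1b differed by 0.31 (adjusted p = 0.121). Il1b was called higher at 0.31 with quantile normalization alone or the deposited log2 values (adjusted p = 0.0492) and with a trended and robust variance (0.0294). The list had a median of 0.11 (adjusted p = 0.015, and adjusted p = 0.42 with an estimated correlation). Tnfaip2 by 0.86 and Nfkbia by 0.84 rose among NF-kB feedback targets (median 0.22, adjusted p = 0.0409, and adjusted p = 0.66 with an estimated correlation). Gpnmb rose by 1.24 ± 0.2 (adjusted p = 0.0127), and Cst7 differed by 1.01 (adjusted p = 0.0751), in the disease-associated list (median 0.07, adjusted p = 0.00703, and adjusted p = 0.46 with an estimated correlation). Sirt1 differed by -0.32 (adjusted p = 0.242).

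Markers of endothelial cells, neurons and astrocytes were higher with age in the same samples, while the oligodendrocyte and choroid plexus lists were not called (adjusted p = 0.259 and 0.203). Endothelial markers were higher (1 of 12 over all probes, 7 when adjusted over the list alone, median 0.89, adjusted p = 5.62e-07, and adjusted p = 0.42 with an estimated correlation). Neurons (median 0.45, 0.000527, and adjusted p = 0.17 with an estimated correlation), with Syp at 0.70 and Stmn2 at 1.16 both called, and astrocytes (median 0.21, 0.00309, and adjusted p = 0.42 with an estimated correlation), with Plpp3 higher by 1.11, were higher too. Mural and meningeal cells at 0.24, neutrophils at 0.40, glycolysis at 0.12, cell cycle at 0.17 (its member Stmn1 rose by 0.59) and erythrocytes at 0.31 were called higher at 0.00515, 0.00309, 0.0141, 0.0153 and 0.0157, which became adjusted p = 0.5, 0.64, 0.17, 0.5 and 0.26 with an estimated correlation. Border-associated macrophage markers were lower (2 of 13 over all probes, 5 when adjusted over the list alone, median -0.41, adjusted p = 0.000206, and adjusted p = 0.46 with an estimated correlation), with Ms4a7 lower by -0.81. Xist was near background on 2 of the 3 old SIRT1F/F arrays and on none of the young SIRT1F/F ones. Of 33 called genes named by the rule, 3 held without any 1 array (Il10, Nbl1 and Gm6377). Of the calls 4, 11, 19, 24, 29 and 19 were lost without young SIRT1F/F 1, 2 and 3 and old SIRT1F/F 1, 2 and 3. Of the 12 list calls those of endothelial cells, neurons, astrocytes and border-associated macrophages held, and 2, 8, 3 and 2 were lost without young SIRT1F/F 1, young SIRT1F/F 2, old SIRT1F/F 2 and old SIRT1F/F 3. Limma called 128 probes higher and 73 lower, and 398, 53, 41, 9 or 119 in all without young SIRT1F/F 1, young SIRT1F/F 3, old SIRT1F/F 1, old SIRT1F/F 2 or old SIRT1F/F 3, and 130 without either TAU array. With the level of Xist as a covariate it called 25, and without the 5 arrays of low Xist or Eif2s3y, which keeps 1 old SIRT1F/F array, 0, with 1398 at an unadjusted p under 0.05.

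In LysM-Cre samples 90 of the probes called higher with age and 43 of those called lower were shared with SIRT1F/F. Slc47a1 rose by 1.93 ± 0.22 (adjusted p = 0.00276), Scara3 by 1.72, Gpnmb by 1.68 ± 0.2 (adjusted p = 0.00295, with its other probes from 0.26), Igfbp5 by 1.56, Nbl1 by 1.52 ± 0.16 (adjusted p = 0.00166) and Fbln1 by 1.52. The mesenchymal factors Foxc2 and Rspo3, which amplifies Wnt signals, rose by 1.72 and 1.64, the heparan sulphate proteoglycan Gpc3 by 1.60 and the collagen gene Col6a1 by 1.59. Foxc2 was above background on 1 of 3 young LysM-Cre arrays and Hal on 2 of 3 old ones. Il10 fell by 1.88 ± 0.24 (adjusted p = 0.00364), Cd55 by 1.58, Hal by 1.79, Hspa1l by 1.69, the integrin Itgad by 1.56, the haem-responsive factor Spic by 1.25 and Clec4a1 by 1.23. Ifng and Lif were not well above background in old LysM-Cre and fell at least 1.29-fold and 2.26-fold. Il1a rose by 1.02 ± 0.19 (adjusted p = 0.0211), Il1b differed by 0.23 (adjusted p = 0.223), and the IL-1 family list had a median of 0.23 (adjusted p = 0.0326, and adjusted p = 0.52 with an estimated correlation). Lyz1, which fell with age in SIRT1F/F and is named here after its values were seen, differed by -0.69 ± 0.37 (adjusted p = 0.359).

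Gene lists moved with age in LysM-Cre mice too. Endothelial markers were higher (7 of 12 when adjusted over the list alone, median 0.83, adjusted p = 3.18e-05, and adjusted p = 0.52 with an estimated correlation), and neurons, with Syp higher by 1.10, had a median of 0.55 (0.00348, and adjusted p = 0.28 with an estimated correlation). Astrocytes at 0.24 (0.00441), mural and meningeal cells at 0.37 (0.00532; Ptgds rose by 1.48), neutrophils at 0.35 (0.00629) and monocytes at 0.29 (0.0474) were higher, with adjusted p = 0.52, 0.52, 0.64 and 0.61 with an estimated correlation. Border-associated macrophages were lower (median -0.35, 0.00447, and adjusted p = 0.59 with an estimated correlation). Of disease-associated genes 2 of 26 rose over all probes and 6 when adjusted over the list alone (median 0.21, adjusted p = 0.000488, and adjusted p = 0.44 with an estimated correlation), with Clec7a, a beta-glucan receptor, higher by 0.63. Glycolysis (median 0.19, adjusted p = 0.000701, and adjusted p = 0.058 with an estimated correlation) included the glucose transporter Slc2a1, which rose by 0.79. Interferon-stimulated genes had a median of 0.31 (adjusted p = 0.000488, and adjusted p = 0.52 with an estimated correlation), with Slfn2 higher by 0.54. Of 33 called genes named by the rule, 11 held without any 1 array (Slc47a1, Gpnmb, Rspo3, Gpc3, Nbl1, Syp, Il10, Cd55, Hspa1l, Itgad and Spic). Of the calls 9, 13, 18, 20, 11 and 11 were lost without young LysM-Cre 1, 2 and 3 and old LysM-Cre 1, 2 and 3. Of the 11 list calls those of the IL-1 family, monocytes, border-associated macrophages, neutrophils and mural cells did not hold. Among them 3 were lost without young LysM-Cre 1 or 2, 2 without old LysM-Cre 1 and 1 without young LysM-Cre 3 or old LysM-Cre 3. Limma called 171 probes higher and 99 lower. It called 158, 146, 74, 50 or 132 without young LysM-Cre 1, young LysM-Cre 2, young LysM-Cre 3, old LysM-Cre 1 or old LysM-Cre 2, 172 without old SIRT1F/F 2, and 1 without the 5 arrays of low Xist or Eif2s3y, which keeps 1 young LysM-Cre array.

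**Figure D4:**
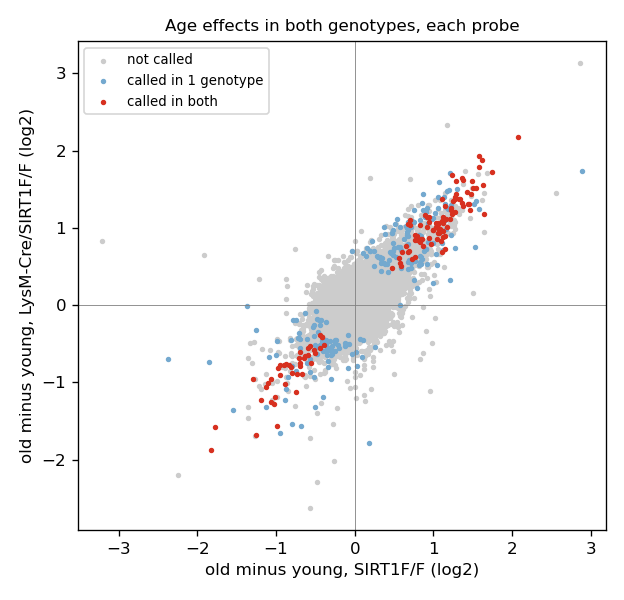
Age effect (old minus young, log2) of each tested probe in SIRT1F/F (horizontal axis) and LysM-Cre (vertical axis), grey where not called, blue where called in 1 genotype and red where called in both. Of the 128 and 171 probes called higher, 90 were shared, and the values correlate at 0.729 across probes.

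No gene's age effect was shown to differ with genotype. The age effects in SIRT1F/F and LysM-Cre, which share no arrays, had 90 called probes in common among the higher ones against 1.3 for independent lists and 43 against 0.429 among the lower ones, with r = 0.729 across probes, which are not independent replicates. The young arrays of the 2 genotypes, the baselines of these effects, were correlated by number (r = 0.23 to 0.50), which adds to the overlap and to r without any age effect, and the values for independent lists leave this out. For the interaction limma called 0 probes higher or lower, with a smallest adjusted p of 1 and 443 probes at an unadjusted p under 0.05. Lyz1, named here after its values were seen, had an interaction of 1.69 ± 0.52 (adjusted p = 1). Il1b stood at -0.08, Lyz2 at 0.07, Mapt at -0.10 and Sirt1 at 0.04. The smallest p belonged to Eif1ax, not well above background in 3 of the 4 groups, Noxo1, an organiser of NADPH oxidase, at 0.73, Tnfsf10 (above background on 1 of 3 young LysM-Cre arrays) at 0.74, Hal (on 2 of 3 old LysM-Cre arrays) at -1.97, Ly6d at -0.80 and Cyp2e1 at -1.54. Camera called 2 lists and fry 0. The genotype effect on interferon-stimulated genes was higher in old than young mice by a median of 0.24 (adjusted p = 0.000383, and adjusted p = 0.96 with an estimated correlation), and that on B cell genes lower by a median of -0.25 (adjusted p = 0.00288, and adjusted p = 0.5 with an estimated correlation). The first lost its call without young SIRT1F/F 1 (adjusted p = 0.125), young LysM-Cre 3 (0.0524) or old SIRT1F/F 3 (0.111), and without the 5 arrays of low Xist or Eif2s3y, which leaves 1 array in 2 of the 4 groups, its median was -0.07 (0.76). The second lost its call without young SIRT1F/F 3 (0.0769), young LysM-Cre 1 (0.0614) or old SIRT1F/F 1 (0.0668).

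TAU samples differed from young SIRT1F/F samples in a set of disease-associated genes. Gpnmb rose by 3.88 ± 0.22 (adjusted p = 1.05e-06, with another probe at 0.33), Cst7, an inhibitor of lysosomal proteases, by 2.96 ± 0.28 (adjusted p = 5.84e-05), the apolipoprotein gene Apoc1 by 2.66 ± 0.16 (adjusted p = 1.05e-06), Ank, a pyrophosphate exporter, by 1.39 ± 0.1 (adjusted p = 6.41e-06) and Clec7a by 1.44 ± 0.16 (adjusted p = 0.000221). Of 26 disease-associated genes 18 rose over all probes, and 18 rose and 1 fell when adjusted over the list alone (median 0.71, adjusted p = 1.49e-13, and adjusted p = 0.025 with an estimated correlation). Homeostatic genes fell in 4 of 21 cases over all probes and 6 when adjusted over the list alone (median -0.26, adjusted p = 0.000235, and adjusted p = 0.21 with an estimated correlation), Tmem119 by 0.62 ± 0.1, the sialic acid lectin Siglech by 0.49, the adenosine receptor Adora3 by 0.79 and the identity factor Sall1 by 0.59. Csf1, the growth factor of microglia, rose by 2.24 ± 0.25 (adjusted p = 0.000226), Tnf by 1.25 ± 0.26 (adjusted p = 0.00951), Tnfsf9 by 1.51 and Cxcl10 by 0.68 (cytokine list median 0.20, adjusted p = 0.0145, and adjusted p = 0.31 with an estimated correlation). Of 17 glycolytic genes 7 rose (median 0.33, adjusted p = 0.000235, and adjusted p = 0.025 with an estimated correlation), Tpi1 by 0.72 ± 0.09, Slc2a1 by 0.96, Aldoa by 0.62 and Ldha by 0.41. Il10 fell by 1.58, Cd55 by 2.04, Hmox1 by 1.58, Clec4a1 by 1.60, the acute phase gene Saa3 by 2.30 and Lyz1 by 2.28 ± 0.41 (adjusted p = 0.00432). Sirt1 fell by 0.46 ± 0.14 (adjusted p = 0.0466). That call was lost in 3 of the alternatives fixed beforehand (adjusted p from 0.0733 to 0.16), with the Xist (0.0619) or oligodendrocyte (0.487) covariate, without the 5 arrays of low Xist or Eif2s3y (0.119), and without young SIRT1F/F 1 (0.119), young SIRT1F/F 3 (0.121), TAU 1 (0.343) or TAU 2 (0.0899). Il1b differed by 0.33 (adjusted p = 0.0536). It was called higher in 7 of the alternatives fixed beforehand, at 0.32 to 0.33 and an adjusted p from 0.0106 with a trended and robust variance to 0.0429 with 1 probe per gene, and without young SIRT1F/F 1 (0.0481). Mak16 fell by 2.75 on 1 probe and differed by 0.08 on another.

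Markers of oligodendrocytes, choroid plexus, astrocytes, mural and endothelial cells and neurons were higher on the TAU arrays, the same 2 arrays that enter the TAU genotype comparison. Mbp rose by 4.28 ± 0.33 (adjusted p = 7.83e-06), Mobp by 3.84, Bcas1 by 3.79, Plekhb1 by 3.17, Car2 by 2.41 ± 0.17 and Olig1 by 2.40. Mog and Opalin, not well above background in young SIRT1F/F, rose at least 4.53-fold and 4.06-fold, and Mobp was above background there on 1 of 3 arrays. Of 13 oligodendrocyte genes 8 rose over all probes (median 2.07, adjusted p = 5.45e-10, and adjusted p = 0.028 with an estimated correlation). Choroid plexus markers (5 of 7, median 1.89, 2.1e-06, and adjusted p = 0.12 with an estimated correlation) included Kl, higher by 2.57, Clic6 by 2.49, Folr1 by 2.34 and Calml4 by 1.89. Of 15 astrocyte genes 10 rose and 1 fell (median 0.87, 3.47e-06, and adjusted p = 0.092 with an estimated correlation), with Clu higher by 1.69 and Sox9, above background on 1 of 3 young arrays, by 1.11. Mural cells (6 of 13, median 0.68, 3.47e-06, and adjusted p = 0.17 with an estimated correlation) had Igfbp2 higher by 2.27 and the pericyte gene Rgs5 by 1.80. Endothelial cells (5 of 12, median 1.15, 7.14e-06, and adjusted p = 0.33 with an estimated correlation) had Slco1a4 higher by 1.62 and Vwf by 1.42, and neurons (3 of 9, median 0.40, 0.000528, and adjusted p = 0.087 with an estimated correlation) had Atp1b1 higher by 2.09. Oxidative phosphorylation at 0.17 (0.000887) and cell cycle at 0.27 (0.00151; Stmn1 rose by 1.51) were higher and neutrophils at -0.39 (0.0413) lower, with adjusted p = 0.12, 0.31 and 0.65 with an estimated correlation. Mapt rose by 1.58 on 1 of 3 probes (adjusted p = 0.000999) and was not called on the others. Of 63 called genes named by the rule, 28 held without any 1 array (among them Gpnmb, Cst7, Apoc1, Ank, Clec7a, Csf1, Tpi1, Mbp, Cd55 and Il10). Of the calls 4, 3, 12, 35 and 18 were lost without young SIRT1F/F 1, 2 and 3, TAU 1 and TAU 2. The neutrophil list lost its call without young SIRT1F/F 1 (adjusted p = 0.37), young SIRT1F/F 3 (0.0702) or TAU 1 (0.486), and the cytokine list without TAU 2 (0.119). Limma called 1018 probes higher and 895 lower. It called 904, 295 or 770 without young SIRT1F/F 3, TAU 1 or TAU 2, and 4 with the level of the oligodendrocyte list as a covariate, which mostly follows the groups.

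Against old SIRT1F/F disease-associated genes again stood out in TAU. Apoc1 rose by 2.69 ± 0.16 (adjusted p = 1.83e-06), Gpnmb by 2.65 ± 0.22 (adjusted p = 2.58e-05), Apoc4 (above background on 2 of 3 old arrays) by 2.35 ± 0.26, the integrin gene Itgax by 2.03 ± 0.27, Igf1 by 1.57 ± 0.16 and Ank by 1.33. Of the 26 listed genes 12 rose over all probes and 14 when adjusted over the list alone (median 0.44, adjusted p = 3.68e-14, and adjusted p = 0.031 with an estimated correlation). Of 21 homeostatic genes 5 fell (median -0.25, adjusted p = 1.11e-05, and adjusted p = 0.12 with an estimated correlation), Upk1b by 1.16 ± 0.19, Adora3 by 0.71, Tmem119 by 0.59 and Siglech by 0.40. Il1b differed by 0.01 (adjusted p = 0.972) and Sirt1 by -0.14 (adjusted p = 0.7). Scd1 by 0.98 and Acaca by 0.71, enzymes of fatty acid synthesis, rose in the cholesterol and lipid list (median 0.11, adjusted p = 0.0209, and adjusted p = 0.26 with an estimated correlation). Srxn1, sulfiredoxin, rose by 0.72 among antioxidant genes (median 0.16, adjusted p = 0.0143, and adjusted p = 0.12 with an estimated correlation), and Tpi1 by 0.54 and Ldha by 0.36 in glycolysis (median 0.21, adjusted p = 0.00956, and adjusted p = 0.077 with an estimated correlation). Oxidative phosphorylation at 0.14 (0.000117, and adjusted p = 0.077 with an estimated correlation) and border-associated macrophages at 0.31 (0.0173, and adjusted p = 0.48 with an estimated correlation) were called higher with none of their members called.

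Markers of neutrophils, monocytes and erythrocytes were lower on these TAU arrays and those of oligodendrocytes, choroid plexus, astrocytes and mural cells higher. Neurons (adjusted p = 0.291), endothelial cells (0.253), T and NK cells (0.281) and B cells (0.24) were not called. Of 16 neutrophil genes Cxcr2, a chemokine receptor, fell by 1.34, and 10 fell when adjusted over the list alone (median -0.86, adjusted p = 5.86e-07, and adjusted p = 0.26 with an estimated correlation). Of monocyte genes Plac8 fell by 1.25 and S100a6 by 0.80 (median -0.55, adjusted p = 0.00207, and adjusted p = 0.26 with an estimated correlation). Of 6 erythrocyte and platelet genes 3 fell (median -0.97, adjusted p = 0.000511, and adjusted p = 0.046 with an estimated correlation), Gp9 by 1.15, and Hbb-b2 and Ppbp, not well above background in TAU, at least 2.83-fold and 1.2-fold. Mbp rose by 4.16 ± 0.33 (adjusted p = 1.32e-05), Bcas1 by 4.42 ± 0.67, Plekhb1 by 3.09, Olig1 by 2.50, Opalin by 2.44, and Mog, Fa2h and Ugt8a at least 4.7-fold, 3.86-fold and 3.27-fold. Opalin was above background on 1 of 3 old SIRT1F/F arrays. Of 13 oligodendrocyte genes 6 were called (median 0.67, adjusted p = 6.97e-11, and adjusted p = 0.031 with an estimated correlation). Choroid plexus (5 of 7, median 1.94, 2.88e-07, and adjusted p = 0.1 with an estimated correlation) had Folr1 higher by 2.03 and Calml4 by 1.98, astrocytes (2 of 15, median 0.45, 0.00114, and adjusted p = 0.22 with an estimated correlation) Ntsr2 by 0.76 and Gfap (above background on 1 of 3 old arrays) by 0.65, and mural cells (3 of 13, median 0.43, 0.000868, and adjusted p = 0.26 with an estimated correlation) Igfbp2 by 1.85, Rgs5 by 1.60 and Vtn by 1.38. Lrrc57, Spint1 and Prkag2 were not well above background in TAU and fell at least 9.87-fold, 4.06-fold and 3.08-fold. Mapt rose by 1.54 on 1 of 3 probes (adjusted p = 0.00236). Of 52 called genes named by the rule, 20 held without any 1 array (among them Apoc1, Apoc4, Gpnmb, Ank, Igf1, Itgax, Mbp, Olig1 and Gp9). Of the calls 13, 23, 13, 29 and 25 were lost without old SIRT1F/F 1, 2 and 3, TAU 1 and TAU 2. The border-associated macrophage list lost its call without old SIRT1F/F 2 (adjusted p = 0.0529) or TAU 2 (0.121), and the lipid list without TAU 1 (0.0585). Limma called 431 probes higher and 185 lower. It called 249, 352, 131 or 200 without old SIRT1F/F 2, old SIRT1F/F 3, TAU 1 or TAU 2, and 223, 3 or 26 with the Xist covariate, with the oligodendrocyte covariate or without the 5 arrays of low Xist or Eif2s3y, which keeps 1 old SIRT1F/F array.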

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

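Of the tests in this part, those of oligodendrocyte RNA, of disease-associated genes, of Lyz2 RNA on the Lyz1 probes and of leukocyte RNA were chosen after the results they bear on were seen, and the differences between genotype effects in TAU and other samples were not among the comparisons fixed beforehand. The genotype effect of LysM-Cre differed between kinds of samples in 50 probes when TAU was compared with young samples (1 higher and 49 lower in TAU, limma) and in 32 probes when it was compared with old ones (2 higher and 30 lower). Among them were myelin genes and genes of the choroid plexus. From young to TAU samples the log2 effect moved by -4.28 for Mbp, -3.72 for Mobp, -3.33 for Plekhb1, -2.97 for Opalin, -2.85 for Olig1, -2.84 for Prr18, -2.71 for Sostdc1, -2.59 for Folr1, -2.53 for Car2, -2.50 for Mog, -2.22 for Fa2h and -2.21 for Omg. From old to TAU samples it moved by -4.10 for Mbp, -3.77 for Mobp, -3.21 for Plekhb1, -2.94 for Prr18, -2.66 for Omg, -2.51 for Olig1, -2.43 for Car2, -2.26 for Mog and -2.19 for Fa2h. These are the probes named in the genotype comparisons. Another called probe of Mobp, the one of lowest p here, moved by less, -1.98 from young and -2.26 from old samples, another of Mog by -2.84 and -2.57, and another of Folr1, also of lowest p, by -2.67 and -2.44. Mog, Fa2h, Opalin, Omg and Mobp were not well above background in TAU/LysM and in most arrays of the young and old groups, so their values are differences of normalized signals near the floor and not exact sizes. These differences were not run without single arrays or with array weights, and groups of 2 or 3 arrays leave little room to judge 1 lying apart.

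Oligodendrocyte transcripts were higher on the 2 TAU arrays than in the other 5 groups, with Mbp at 11.74 in TAU and at 7.12 in TAU/LysM. On intensities with no correction the median difference of the oligodendrocyte list from the other 5 groups was 1.11, against 1.16 after normalization, which argues against background correction and normalization as the source. A lower share of microglia stays open. In TAU neutrophils differed by -0.80 (SE 0.23) and oligodendrocytes by 1.5 (SE 0.16). Neutrophils, being myeloid, may be selected too, and astrocyte genes rose against SIRT1F/F. RNA of oligodendrocytes left in the separated cells remains a candidate explanation, since 61.5% of the list (8 of 13 measured genes, none of them on another list) lay above all 14 other arrays on both TAU arrays, a share that decides neither way, and the protocol removes myelin on beads. It cannot be told apart from the unstated age of these mice, the handling of 2 samples or an effect of TAU that is absent with LysM-Cre, which stay open, while the TAU genotype alone is argued against by TAU/LysM, where the list differed from old LysM-Cre by 0.07 (SE 0.19) and from young LysM-Cre by 0.15 (SE 0.19).

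Lyz1 was higher with LysM-Cre on 2 of its 3 probes in the old and TAU samples. Lyz2 RNA binding to those probes is argued against, since Lyz2 itself averaged -0.26. RNA of neutrophils or monocytes is argued against as well, because the largest rise among 26 other markers in the old groups, that of Mpo, was 0.92 ± 0.5, below the Lyz1 rise of 3.73 ± 0.37 by 2.8 ± 0.62. A stretch of another strain's chromosome that altered several neighbours of Lyz2 had its test fixed beforehand, and 15.2% of 79 tested neighbours had an unadjusted p under 0.05 for the average genotype effect, at the 22.4 percentile of 9709 windows of the genome (median 18.8%), with none of them called. A strain variant in Lyz1 alone may still account for it, as may the Cre insertion in Lyz2 or the loss of SIRT1, and no group is labelled as carrying Cre without the floxed gene, while the labels of TAU/LysM leave its floxed genotype unstated.

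Disease-associated microglia genes were higher on the TAU arrays. Their median difference from the other 5 groups was 0.41 on uncorrected intensity and 0.42 after normalization, which argues against background correction and normalization. Carry-over with the oligodendrocyte RNA is argued against by TAU/LysM. Its mean level of this list exceeded old LysM-Cre by 0.94 (SE 0.08), that of oligodendrocytes by 0.07 (SE 0.19). The TAU genotype is a candidate. The age of old SIRT1F/F is argued against, with levels of -0.262 to -0.079 there and 0.497 and 0.618 in TAU. An older age and handling were not tested.

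Other splits of the same arrays were counted for the comparisons of groups of at least 3 arrays. Each pair of groups allows 10 splits, too few for a share under 0.05. The real split called 0 probes for the young genotype comparison (1329 at an unadjusted p under 0.05) and the highest other 14. It called 3 for the old genotype comparison and the highest other 0. For the age effect in SIRT1F/F it called 201 and the highest other 0, and for that in LysM-Cre 270 and the highest other 1. For the average genotype effect 6 of 100 drawn splits called at least the 133 probes of the real one, and the highest called 376, so chance could not be excluded. For the interaction the real count was 0 (443 at an unadjusted p under 0.05), which all 100 drawn splits equal or pass by construction, so the count says nothing about chance, and the highest called 241. The same-numbered young arrays, which were correlated, may be the structure behind the splits with many calls. For the average, 31 other splits that parted all 3 young pairs, as the real one does, called at most 46, and the 68 that parted 1 pair up to 376. For the interaction the highest were 4 and 241, and for the young comparison 0 and 14. This grouping of the splits was chosen after the pairs had been seen.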

How the results depend on the processing

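The fits with the level of Xist or of the oligodendrocyte list as a covariate and the fit without 5 arrays were chosen after seeing the data. The 5 arrays have a normalized level under 7 for Xist or Eif2s3y (young LysM-Cre 2 and 3, old SIRT1F/F 2 and 3, and TAU/LysM 1), a rule set after their levels were seen, and young LysM-Cre, old SIRT1F/F and TAU/LysM keep 1 array each, assumed to vary like the other groups. The slide was not run as a block, since the files used here name none, and the detection values asked for were replaced by a background estimate. Under the alternatives fixed beforehand, arrays left out aside, Sirt1 and Il1b kept their direction in all 9 comparisons, but not all of their calls. Il1b was called higher in TAU against young in 7 of them and with age in SIRT1F/F in 3, Lyz2 lower in the genotype average in 8, the replicate block among them, and Sirt1 lost its call in TAU against young in 3. Of 249 named gene values called, 244 kept their call with quantile normalization alone or the deposited log2 values, 247 with an offset of 50, 188 without a filter, all 245 that could be tested with a stricter filter, 241 with the replicate block, 153 with only the groups compared, 249 with array weights, 243 with a trended and robust variance and 224 of 225 with 1 probe per gene. With the Xist covariate 185 were kept, with the oligodendrocyte covariate 63 (23 reversed), and without the 5 arrays 78. Signal over background limits the probes dim in a whole group, for which a bound is given. Of the list calls, 6 of 99 held with an estimated correlation.

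These counts of probes moved by over 1.5 times. The old genotype count was 0 with 1 probe per gene (771 at an unadjusted p under 0.05, limma) and 0 without the 5 arrays (546). The TAU genotype count was 38 with only the groups compared (7.9% of them higher, against 20.8%), 451 with array weights (32.4% higher), 1 with the oligodendrocyte covariate and 32 without the 5 arrays (6.2% higher). The average genotype count was 441 with quantile normalization alone and with the deposited log2 values, 353 with an offset of 50, 50 without a filter (46.0% higher, against 60.9%), 318 with a stricter filter, 412 with array weights, 340 with a trended and robust variance, 277 with 1 probe per gene, 33 with the oligodendrocyte covariate (72.7% higher) and 0 without the 5 arrays. The count for age in SIRT1F/F was 104 without a filter, 20 with only the groups compared (90.0% higher, against 63.7%), 331 with array weights, 25 with the Xist covariate and 0 without the 5 arrays. That for age in LysM-Cre was 127, 135 (77.0% higher, against 63.3%), 460 and 169 under the same 4 settings and 1 without the 5 arrays. TAU against young SIRT1F/F gave 1205 without a filter, 389 with only the groups compared (80.2% higher, against 53.2%), 4 with the oligodendrocyte covariate and 1031 without the 5 arrays (63.7% higher). TAU against old SIRT1F/F gave 393 without a filter, 1483 with array weights (55.0% higher, against 70.0%), 223 with the Xist covariate, 3 with the oligodendrocyte covariate and 26 without the 5 arrays (92.3% higher). The filter changes how many probes are tested, and leaving out 5 arrays keeps 11. The oligodendrocyte covariate lies to 90.2% between groups, so that it takes group differences with it, against 35.2% for Xist. For the other settings the cause was not tested.

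The replicate number as a block gave 304 probes for the average genotype effect, 446 for age in SIRT1F/F and 528 for age in LysM-Cre, with 0 for young, 2 for old, 336 for TAU, 0 for the interaction, 1927 for TAU against young and 695 for TAU against old. In the young genotype comparison, whose arrays the numbers pair, the block ended the call of the homeostatic list and changed no other call. Elsewhere it ended the Sirt1 call in TAU against young (-0.44, adjusted p = 0.0733) 7 other calls of named genes, and the calls of monocytes for age in LysM-Cre and of neutrophils in TAU against young. Deviations of the 36 same-numbered pairs across groups correlated at -0.17 to 0.50, over 0.1 in 11. Outside the young groups the numbers were not taken as pairs. Old LysM-Cre 2 and 3 correlated with young arrays of their number at 0.24 to 0.45, and array 1 at -0.02 and 0.08. Old groups correlated best by number at 0.04 to 0.07.

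With the oligodendrocyte covariate these differences changed sign. In the TAU genotype comparison Lyz2 stood at 0.29, Bcas1 at 0.87 and Map2 at 0.06, and the list medians of oxidative phosphorylation at 0.00, astrocytes at 0.60, oligodendrocytes at 0.08 and endothelial cells at 0.68. In the average Bcas1 stood at 0.12, astrocytes at 0.14, oligodendrocytes at 0.03 and choroid plexus at 0.14. Against young SIRT1F/F, TAU values were -0.40 for Lyz2, -2.08 for Bcas1, -0.08 for Plekhb1, 1.61 for Ciart, -0.36 for Plpp3, -0.33 for Map2, -0.30 for Flt1, -0.17 for Esam, -0.71 for Vwf, -0.48 for Rgs5, -0.62 for Ptgds and -0.50 for Vtn, with list medians of 0.06 (homeostatic), -0.31 (astrocytes), -0.14 (oligodendrocytes), -0.35 (endothelial) and -0.48 (mural). Against old SIRT1F/F they were -0.28 for Lyz2, -0.08 for Il1b, -0.85 for Bcas1, 0.90 for Lrrc57, 0.22 for Spint1, 0.12 for Serpinb2, -0.36 for Scd1, -0.45 for Rgs5, -0.42 for Vtn, -0.08 for Kl and -0.02 for Clic6, with list medians of 0.06 (homeostatic), -0.09 (cholesterol and lipid), -0.74 (border-associated macrophages), -0.41 (astrocytes), -0.08 (oligodendrocytes) and -0.45 (mural). With the Xist covariate Lyz2 stood at 0.00 for age in SIRT1F/F and -0.04 for the interaction, Mapt at 0.02 for the interaction and Il1b at -0.02 for TAU against old. Without the 5 arrays Sirt1 stood at 0.00 for the young genotype comparison, Lyz2 at 0.01 for age in SIRT1F/F and in LysM-Cre and at -0.01 for the interaction and TAU against old, and the list medians of mural cells for age in LysM-Cre at -0.05 and of interferon-stimulated genes for the interaction at -0.07. Lyz2 also stood at 0.02 for age in LysM-Cre with array weights and at -0.03 for TAU against young with the replicate block. The cause of these sign changes was not tested.

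Leaving out each of the 16 arrays in turn gave 0 to 8 probes for the young genotype comparison, 2 to 3 for the old, 28 to 305 for the TAU, 28 to 479 for the average, 9 to 398 for age in SIRT1F/F, 50 to 372 for age in LysM-Cre, 0 for the interaction, 295 to 2002 for TAU against young, 131 to 681 for TAU against old, and 86 to 107 of the list calls. Values that changed sign without some array were all of genes not called. Sirt1 ran from -0.07 to 0.11 in young, -0.02 to 0.15 in old and -0.05 to 0.16 in TAU samples and from -0.05 to 0.14 for the interaction. Lyz2 ran from -0.14 to 0.01 for age in SIRT1F/F, -0.07 to 0.03 in LysM-Cre, -0.02 to 0.12 for the interaction and -0.05 to 0.09 for TAU against young. Mapt ran from -0.23 to 0.07 for the interaction and Il1b from 0.00 to 0.02 for TAU against old.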

Other observations

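The comparisons of TAU/LysM with the LysM-Cre groups were chosen after the others had been seen and were not run under the alternatives. TAU/LysM samples had higher disease-associated genes than LysM-Cre samples of either age. Against young LysM-Cre, Gpnmb rose by 5.11 ± 0.22 (limma adjusted p = 4.35e-08), Cst7 by 3.46 ± 0.28 (adjusted p = 1.25e-05), Apoc1 by 3.25 ± 0.16 (adjusted p = 7.48e-08), Itgax by 2.52, lipoprotein lipase, Lpl, by 2.40 ± 0.23 (adjusted p = 7.03e-05), Igf1 by 2.10 and Clec7a by 2.01. Against old LysM-Cre, Apoc1 rose by 3.69 ± 0.16 (adjusted p = 2.79e-08), Gpnmb by 3.42 ± 0.22 (adjusted p = 2.86e-06), Cst7 by 2.90, Igf1 by 2.27 ± 0.16, the fatty acid binding protein Fabp3 by 2.09, Lpl by 1.58, the receptor Axl by 1.17 and Apoe by 0.66. Of the 26 measured genes of the list 18 and 13 rose over all probes, and 20 and 17 when adjusted over the list alone (camera adjusted p = 3.03e-23 and 6.19e-23, and adjusted p = 0.0048 and 0.005 with an estimated correlation). The receptor Trem2 and its adaptor Tyrobp were not called, with Trem2 at 0.06 in both and Tyrobp at 0.19 and 0.18. Limma called 558 probes higher and 605 lower against young LysM-Cre, and 227 higher and 118 lower against old LysM-Cre.

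Homeostatic genes were lower in TAU/LysM, 11 of 21 against young and 7 against old LysM-Cre over all probes and 15 and 13 when adjusted over the list alone (camera adjusted p = 7.11e-10 and 4.42e-10, and adjusted p = 0.064 and 0.085 with an estimated correlation). Interferon-stimulated genes were higher, with 11 of 20 called against young and 1 against old LysM-Cre (camera adjusted p = 9.63e-12 and 4.72e-08, and adjusted p = 0.22 and 0.33 with an estimated correlation). Glycolysis was called higher against young LysM-Cre only, with 5 of 17 genes (camera adjusted p = 0.000251, and adjusted p = 0.019 with an estimated correlation), and had an adjusted p of 0.13 against old. Neutrophil genes were lower against old LysM-Cre, with 7 of 16 when adjusted over the list alone (median -0.81, camera adjusted p = 7.9e-06, and adjusted p = 0.33 with an estimated correlation). The oligodendrocyte list was not called in either comparison (adjusted p = 0.497 and 0.603), and its probe of Mbp differed by -0.11 ± 0.65 and 0.50 ± 0.65.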
